A study of Mus musculus with 6 samples.

How the data were processed

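Messenger RNA of mouse bone marrow-derived mast cells was measured on 6 single-colour Cy3 Agilent whole-genome arrays, 1 array for each of 6 groups. Per the labels, each hybridised RNA was a pool of 3 samples, so the spread between cultures was averaged before hybridisation and no group had a replicate. Mast cells were grown from bone marrow in interleukin-3 (10 ng/ml) and, in 4 of the groups, kept for 4 days on Swiss 3T3 fibroblasts, an established mouse embryo line, with stem cell factor (100 ng/ml). Per the labels' protocols, mast cells were then taken either as the cells that stayed nonadherent after trypsin treatment and reseeding or by magnetic beads against CD117 (Kit). Which of these routes the arrayed RNA came from, and whether the cultures without fibroblasts received stem cell factor, is not given in the sources used here.

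The scanner intensity of each spot was extracted by the authors with Agilent Feature Extraction 12.1.1.1, per the file headers, which also record spatial detrending, background subtraction and a surrogate value for dim spots. These steps leave a positive processed intensity for nearly any spot, so low values rest partly on the surrogate. The deposited value table holds a linear signal: on every array it equalled the processed intensity divided by 1 constant, the 75th percentile recorded by the scanner software (1268.76, 1230.44, 1469.88, 1243.09, 1520.37 and 1458.71 for Pla2g3+/+ and Pla2g3-/- cells alone, the same pair in coculture, and wild-type and Lpar1-/- fibroblasts). The medians of its columns were 0.0401, 0.0380, 0.0485, 0.0498, 0.0471 and 0.0534. Its scale and direction were therefore settled, and no centring of genes was found. The well-above-background, saturation and outlier marks were taken as deposited.

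The main setting was log2 of the processed intensity minus the 75th percentile of that array over its 43020 noncontrol spots. Spots marked as outliers by the scanner software (84 to 115 per array) were dropped, and spots of 1 probe were averaged, which left 39416 of 39429 probes. No spot was saturated. Accessions named 33002 spots through the gene table of assembly GRCm38.p6, used for names alone. Symbols named 3072 further spots, synonyms named 16, and 6930 kept the name in the file. Of the 29590 genes, 7563 had several probes, and the probe with the highest mean over the 6 arrays stood for the gene. Probe coordinates are those of the files, on mm9. No mm9 annotation was used here, so exon or untranslated region is not stated for any probe.

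A gene was compared where at least 1 of the arrays was well above background, and was counted as higher or lower at a difference of at least 2-fold. Where 1 array was not well above background, the difference is a bound ("at least N-fold"), taken against the higher of the lowest signal among probes well above background on that array and the dim probe's own. A gene counted as not above background only when all of its probes were not. With 1 array per group there is no replicate check, no p-value is given, and the number of arrays limits the precision of every value. The scanner software's error model put the error of a spot at 10.0% or more of its signal, and the median error of the difference for a named gene was 0.20 on the log2 scale. That error covers the spot and not the culture.

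The pair of wild-type cocultures, on the same slide, served as a yardstick: the standard deviation of their log2 differences was 0.26, and 95% of them lay within 0.54. Whether their mast cells came from the same animals is not given in the sources used here. The arrays without fibroblasts lay on slide 1 and the cocultures on slide 2, so slide and coculture cannot be told apart. Genotype comparisons lay within a slide, and the slide cancels in the difference between the coculture effects of both mast cell genotypes.

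For 23 gene lists, the median log2 difference was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list was called apart below percentile 2.5 or above percentile 97.5. The other list had too few measured members. In the yardstick pair 10 of 22 tested lists were apart with medians up to 0.25 in size, so only lists that were apart with a larger median are described as higher or lower. That last condition was added after the values were seen. Percentiles describe these arrays and are not p-values over cultures. Correlations across genes were computed for 3 pairs of comparisons, none of which shared an array. Genes are not independent replicates, so no p is given for them.

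Groups, comparisons, gene lists, the 2-fold rule, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule took 15 fixed genes, the 8 highest and 8 lowest genes of each main comparison among those well above background on both arrays, the 3 largest bounds per direction, and up to 3 highest and 3 lowest members past 2-fold of each list. Where a wild-type coculture array was used, the top genes and bounds also had to pass with the other wild-type array in its place. Clone names, unnamed loci and olfactory or vomeronasal receptors were passed over. Of the 269 genes named by the rule, a choice is printed. The probes of Fat1 and of Cplx2 disagreed with each other, so no direction is given for these genes in the main setting.

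Other settings tried were normexp background correction (limma 3.58.1 in R 4.3.3, offset 50), quantile normalization, median centring, the deposited value table, 2 other treatments of dim probes, measured differences in place of bounds, the mean over probes, and the other wild-type coculture array. Added after seeing the data were a minimum of -5 for the brighter array, a restriction to genes at or above -3 on both arrays without fibroblasts, and the other array without fibroblasts as baseline. Everything else ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

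The procedure was tested on simulated data built for the Pla2g3 comparison in coculture with 29590 genes. Of 50 genes planted per size, it recovered 98% at a log2 change of 1.5, 94% at -1.5, 100% at 3 and 94% at -3, while 0.929% of 23465 unchanged genes passed 2-fold. Of 200 unchanged lists of 20 genes, 3.5% were called apart, and 100% of lists shifted by 0.5 were called above. These lists were random genes with noise drawn gene by gene, so they lack the shared movement of real lists. Of the real lists, 10 of 22 were apart in the wild-type pair, so 3.5% does not apply to them. The noise came from that same pair, so the 0.929% only restates its 0.97% of genes past 2-fold.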

Results

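The arrays covered mast cells without fibroblasts with Pla2g3+/+ or Pla2g3-/- genotype, both of these in coculture with wild-type fibroblasts, and wild-type mast cells in coculture with wild-type or with Lpar1-/- fibroblasts. Pla2g3 encodes a secreted phospholipase A2, and Lpar1 a receptor for lysophosphatidic acid. The design asks how coculture, mast cell Pla2g3 and fibroblast Lpar1 relate to the maturation of mast cells toward the connective tissue type. The 75th percentile of signal was 1268, 1230, 1469, 1243, 1520 and 1459 on the 6 arrays in that order, and 70.7% to 80.4% of spots were well above background. In all, 19746 of 29590 genes were well above background on every array. The wild-type coculture arrays differed from each other at least 2-fold in 193 genes upward and 40 downward of 24025, with a correlation of 0.998 across genes (82.8% of these differences upward, and 45.7% after quantile normalization).

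Pla2g3, the targeted gene, went against its label. Its brightest probe (chromosome 11, 3394109 to 3394168, mm9) read 0.51 on the array labelled Pla2g3-/- without fibroblasts and -6.31 on the Pla2g3+/+ array, a 113-fold higher signal under the Pla2g3-/- label. In coculture it read -1.84 under that label and -7.31 under Pla2g3+/+, a 44.4-fold higher signal. The probe at 3399294 to 3399353 was at least 42.8-fold and at least 23.6-fold higher in the same comparisons, and the probe at 3393127 to 3393186 at least 16.1-fold and at least 2.76-fold. The deleted part of the allele is not given in the sources used here, so it is not known whether these probes lie in it, and a probe outside it checks nothing. With wild-type mast cells, the brightest probe read -6.58 on wild-type and -4.85 on Lpar1-/- fibroblasts. This genotype is therefore written as the array labelled Pla2g3-/- throughout, and each direction drawn from it rests on that label. Lpar1 was deleted in the fibroblasts, whereas the RNA was taken from the mast cell fraction, in which fibroblast transcripts were also abundant. Its probe (chromosome 4, 58499672 to 58499731) was brighter without fibroblasts than in any coculture. The Lpar1 signal therefore need not come from fibroblasts, and the probe does not check the Lpar1-/- label. Lpar1 read -4.14 with wild-type and -3.89 with Lpar1-/- fibroblasts, -4.34 and -3.58 in the Pla2g3+/+ and Pla2g3-/- labelled cocultures, and -2.84 and -2.85 without fibroblasts.

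**Figure D1:**
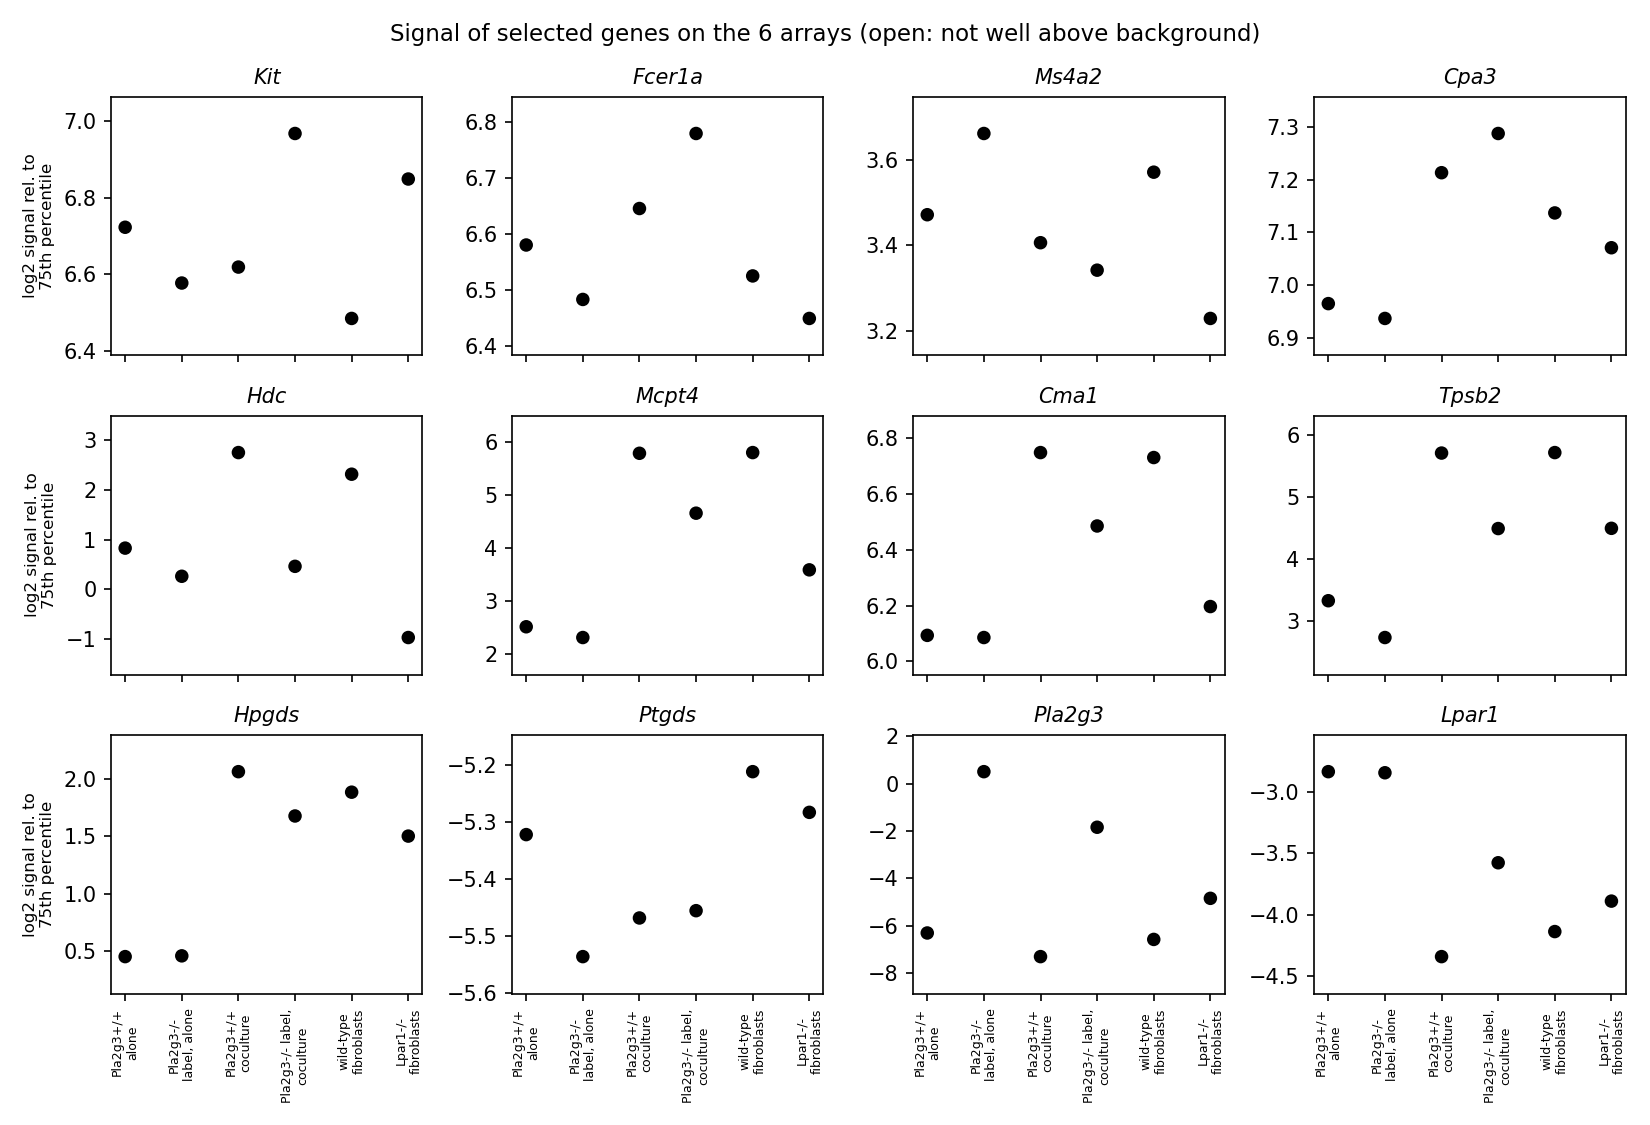
Log2 signal relative to the 75th percentile of each array (vertical axis, a separate scale per panel) for 12 genes on the 6 arrays (horizontal axis), 1 point per array and no error bars because each group had 1 array. Pla2g3 reads 0.51 and -1.84 on the arrays labelled Pla2g3-/- and at most -4.85 on the others.

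Coculture of Pla2g3+/+ mast cells with fibroblasts was accompanied by a higher signal of connective tissue mast cell genes. Tpsab1, the alpha/beta-1 tryptase (chromosome 17, 25480640 to 25480699), was 210-fold higher, and the mast cell receptor genes Mrgprb2 and Mrgprb1 were 87.4-fold and at least 521-fold higher. The chymase Mcpt4 (chromosome 14, 56678589 to 56678648) was 9.68-fold, the tryptase Tpsb2 5.18-fold, the histidine decarboxylase gene Hdc (chromosome 2, 126419516 to 126419575) 3.79-fold, and the prostaglandin D synthase Hpgds 3.06-fold higher. Of 12 measured members of the connective tissue list, 7 were higher, 0 lower and 5 within 2-fold (median 2.15, percentile 100). Kit (-0.10), Fcer1a (0.07), Ms4a2 (-0.07), Cpa3 (0.25), Cma1 (0.65), Ndst2 (0.26) and Ptgds (-0.15) stayed within 2-fold on the log2 scale, and Ptgdr was not well above background on any array.

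In the same comparison 35 of 44 cell cycle genes were higher and 0 lower (median 1.23, percentile 100), among them the mitotic kinase gene Aurkb (5.18-fold) and the replication licensing genes Cdc6 (4.18-fold) and Cdt1 (3.70-fold). Immediate early genes, which respond to stimulation within minutes, were higher in 16 and lower in 1 of 32 (median 1.09), with Egr3 20.8-fold and Fosl1 16.8-fold higher and Fos 2.65-fold lower. Cytokine genes went both ways, 11 higher and 11 lower of 29 (median 0.54), and this list was no longer apart with normexp, quantile normalization, the mean of probes or the other filters on dim probes. Tnf was 14.1-fold and Cxcl1 at least 219-fold higher, whereas Il1b was 18.3-fold and Lif 6.58-fold lower. The mucosal list, named so for short, also holds basophil type proteases and integrins. It was higher in 3 and lower in 3 of 9 (median 0.57, percentile 97.6, a call lost with normexp). Mcpt1 was 20.1-fold and Mcpt2 5.56-fold higher, and Itgae 5.33-fold and Itgb7 3.52-fold lower. Integrin and adhesion genes were higher in 15 and lower in 6 of 32 (median 0.75, percentile 100), with Vcam1, also a fibroblast list gene, at least 261-fold and Itgb5 27.4-fold higher and the cadherin gene Cdh1 15.8-fold lower. Cholesterol synthesis genes moved little, with 0 of 24 past 2-fold but a median of 0.50 at percentile 99.99. Interferon response genes were lower in 12 and higher in 1 of 33 (median -0.55), with Mx1 5.58-fold and Rtp4 4.41-fold lower. Unfolded protein and amino acid response genes were lower in 4 and higher in 0 of 29 (median -0.38), with Chac1 5.66-fold and Trib3 3.48-fold lower, and with the other wild-type coculture array the median was -0.23, not past the yardstick. Among lipid genes, the lysophosphatidic acid producing enzyme Enpp2 was at least 7.07-fold, Lpar2 19.0-fold and Lpar4 17.5-fold higher, and Lpar6 was 11.9-fold and the leukotriene B4 receptor Ltb4r1 26.0-fold lower. The medians of the eicosanoid list (-0.20) and of the phospholipase A2 and lysophosphatidic acid list (0.00) were not past the yardstick.

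Signal of other cell types moved with this comparison. Fibroblast and matrix genes were higher in 37 and lower in 3 of 47 (median 3.64), including Col1a1 (601-fold), Col1a2 (505-fold) and Sparc (393-fold), and of the 3 lower ones Timp3 was 48.2-fold and Thy1 40.7-fold lower. Neutrophil and eosinophil genes were lower in 19 and higher in 1 of 25 (median -2.81), including the eosinophil granule gene Prg2 (251-fold) and the neutrophil granule gene Ngp (26.0-fold). Cd24a was 136-fold lower. Cyp4a12a and Cyp4a12b (479-fold and 378-fold lower) and Dnah7b (534-fold lower) belong to families with near-identical members, and their identity is uncertain. With the array labelled Pla2g3-/- without fibroblasts as baseline, the granulocyte median was -0.01 and that of the connective tissue list 2.73. In all, 2948 of 22615 genes were higher and 1700 lower (63.4% higher, and 48.8% after quantile normalization). With the other wild-type coculture array, 2949 were higher and 1739 lower, of which 2446 and 1496 were shared. Arrays without fibroblasts and cocultures lay on different slides, so slide and coculture cannot be told apart here or in the next comparison. Stem cell factor was given in the cocultures and is not stated for the other cultures, so it cannot be set apart either. With fibroblast transcripts in this RNA, the cell of origin is not settled for genes that both cells express. That holds for any such cell cycle, immediate early or cytokine genes above.

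**Figure D2:**
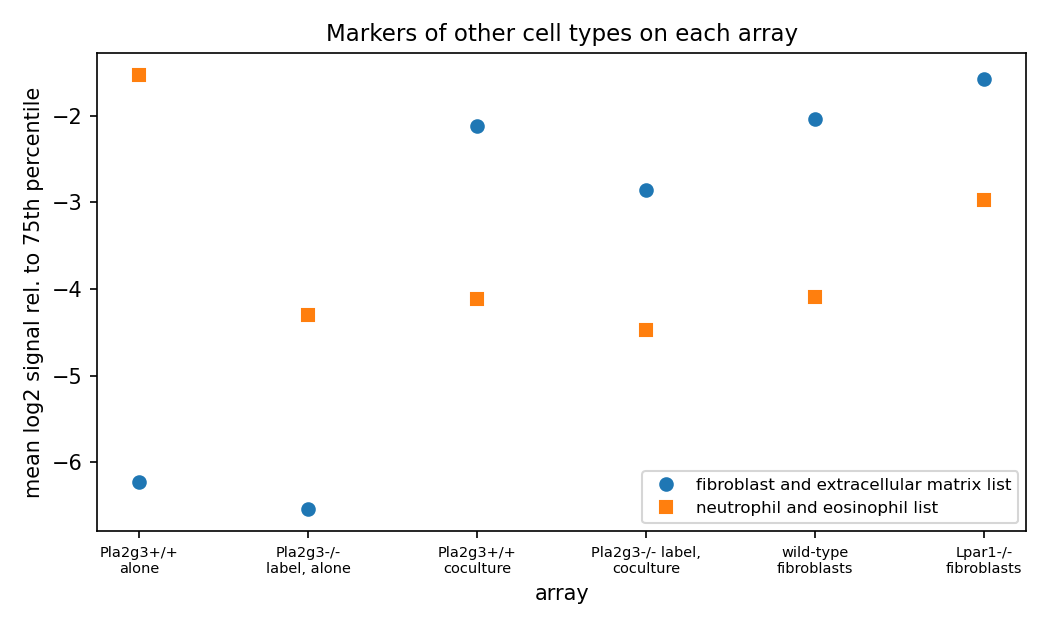
Mean log2 signal relative to the 75th percentile (vertical axis) of the fibroblast and matrix list (circles) and of the neutrophil and eosinophil list (squares) on each array (horizontal axis), 1 value per array and no error bars. The fibroblast list lies at -6.24 and -6.55 without fibroblasts and between -2.86 and -1.58 in coculture, and the granulocyte list is highest, at -1.52, on the Pla2g3+/+ array without fibroblasts.

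For mast cells labelled Pla2g3-/-, coculture was also accompanied by higher connective tissue genes, while genes of growth were lower. Tpsab1 was 55.2-fold, Mrgprb2 41.3-fold, Mcpt4 5.09-fold and Tpsb2 3.37-fold higher, and Hpgds was 2.33-fold higher. Hdc, at 0.20 on the log2 scale, stayed within 2-fold. The mucosal type chymases Mcpt1 and Mcpt2 were 363-fold and 26.5-fold higher, while the mucosal list as a whole (median 0.28, percentile 76.1) was not apart. Of 12 connective tissue genes, 6 were higher and 0 lower (median 1.23, percentile 100). Tnf was 25.5-fold, the immediate early gene Fosb 36.7-fold, the signalling phosphatase Dusp6 21.5-fold, the transferrin receptor Tfrc 14.9-fold and the cysteine synthesis gene Cth 151-fold lower.

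Among the lists of this comparison, cell cycle genes were lower in 19 and higher in 0 of 43 (median -0.93), with the topoisomerase Top2a 2.90-fold and Ube2c 3.06-fold lower. Cholesterol synthesis genes were lower in 17 and higher in 0 of 24 (median -1.32), with Hsd17b7 6.73-fold, Fdps 4.85-fold and Mvd 4.38-fold lower. Genes of the unfolded protein and amino acid response were lower in 19 and higher in 0 of 29 (median -1.27), with Chac1 28.5-fold and Trib3 17.1-fold lower. Interferon response genes were lower in 9 and higher in 3 of 32 (median -0.37), with Rtp4 at -3.46 on the log2 scale and Irf7 5.05-fold lower, and hypoxia and glycolysis genes lower in 6 and higher in 3 of 27 (median -0.55), with Pdk1 3.90-fold lower and Adm 5.04-fold higher. Immediate early genes were lower in 15 and higher in 3 of 32 (median -0.71), and cytokine genes lower in 12 and higher in 3 of 26 (median -0.73), with Il13 9.28-fold lower. Integrin and adhesion genes were higher in 13 and lower in 0 of 31 (median 0.53), with Itgb5 at least 77.3-fold, Vcam1, also a fibroblast list gene, at least 61.5-fold and Itgae 4.62-fold higher, a call lost with normexp. Fibroblast and matrix genes were higher in 40 and lower in 3 of 47 (median 3.20), Col1a1 by at least 495-fold, and the neutrophil and eosinophil list had a median of 0.03. Of 22349 genes, 2547 were higher and 1631 lower (61.0% higher, and 50.3% after quantile normalization).

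The coculture differences of both mast cell genotypes, which share no array but span the same slides, correlated across 19768 genes with r = 0.57 and rho = 0.41. Of the 2-fold genes, 915 were higher in both, where independent lists would share 220, 501 were lower in both, against 102, and 206 went in opposite directions. The direct difference of these effects, in which the slide cancels, was at least 2-fold upward in 2212 and downward in 2416 of 23139 genes. Fibroblast RNA was part of both coculture differences, with fibroblast list medians of 3.64 and 3.20. Among genes expressed without fibroblasts, 845 were higher for Pla2g3+/+ cells and 684 under the Pla2g3-/- label. The genes higher in both therefore do not by themselves show a mast cell response common to both genotypes.

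Without fibroblasts, the arrays of both mast cell genotypes were close, with a correlation of 0.996, and the most strongly lowered genes included members of the neutrophil and eosinophil list. On the array labelled Pla2g3-/-, the eosinophil genes Prg2 and Ear2 were 41.2-fold and 31.2-fold lower, the neutrophil genes Camp, Stfa1 and S100a8 differed by -4.88, -4.84 and -4.64 on the log2 scale, and Pf4 and Ppbp, known as platelet chemokine genes, were 27.7-fold and at least 43.9-fold lower. Neutrophil and eosinophil genes were lower in 18 and higher in 0 of 24 (median -2.87), and macrophage and dendritic genes lower in 10 and higher in 0 of 24 (median -0.72), with Mpeg1 5.13-fold and Mrc1 3.81-fold lower. Higher under the label, besides Pla2g3, were Trim12a (169-fold), Tescl (56.7-fold), the aspartic protease Ctse (25.3-fold), Ppm1n (at least 17.6-fold) and Trim5 (at least 11.8-fold). Trim12a and Trim5, like Ear2, Stfa1, the Mcpt chymases, the tryptases and the Mrgprb receptors, have close relatives that a probe could share, so the member is uncertain.

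Mast cell genes differed less in the cells without fibroblasts. Mcpt4 (-0.20), Tpsb2 (-0.59), Hdc (-0.57), Cma1 (-0.01), Cpa3 (-0.03), Kit (-0.15), Fcer1a (-0.10) and Hpgds (0.01) stayed within 2-fold on the log2 scale. Tpsab1 was 3.20-fold lower, the basophil type proteases Prss34 and Mcpt8 were 6.22-fold and 2.61-fold lower, and Il5 was 2.44-fold lower. The connective tissue list had a median of -0.09 (percentile 3.32), with 1 of 11 members lower. The mucosal list was lower (median -0.31, percentile 0.02), and its 2 of 9 members past 2-fold were the basophil type Prss34 and Mcpt8. Its chymases Mcpt1 and Mcpt2 and its integrins Itgae and Itgb7 stayed within 2-fold. Medians of the cell cycle (0.18), cholesterol (0.07), immediate early (0.04), unfolded protein (-0.01) and cytokine (-0.01) lists did not pass the yardstick. In all, 92 of 21752 genes were higher and 344 lower (21.1% higher).

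In coculture, the array labelled Pla2g3-/- had lower signal of stimulation, growth and connective tissue mast cell genes than the Pla2g3+/+ array. Tnf (chromosome 17, 35336795 to 35336854) was 366-fold, Fosb 112-fold, Nr4a1 48.6-fold, Egr2 42.8-fold and the chemokine Ccl7 33.7-fold lower. Mrgprb1 was 69.4-fold, Hdc 4.88-fold, Tpsb2 2.32-fold, Mcpt4 2.19-fold and Enpp2 at least 7.07-fold lower, and Tpsab1 differed by -3.60 on the log2 scale. Of 12 connective tissue genes, 6 were lower and 0 higher (median -0.70, percentile 0.01). With no filter on dim probes the percentile call was lost (median -0.26).

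Several mast cell genes fixed for naming stayed within 2-fold in this comparison, with Cma1 at -0.26, Hpgds at -0.39, Ms4a2 at -0.06, Cpa3 at 0.07, Fcer1a at 0.13, Kit at 0.35 and Ndst2 at 0.46 on the log2 scale. In the core mast cell list (median 0.11, percentile 96.3, not apart), 3 of 25 genes were higher, Ikzf2 3.79-fold, Stat5a 2.88-fold and Csf2rb 2.19-fold, and 1 was lower, the signalling regulator Rgs13, by 5.61-fold. The mucosal list was split, with 4 of 9 members higher and 5 lower, and its median (-1.01) and mean (0.65) differed in sign. Mcpt1 was 14.6-fold, the integrin genes Itgae 25.4-fold and Itgb7 4.66-fold higher, whereas Mcpt8 was 3.94-fold and Prss34 2.22-fold lower. The mucosal median became 0.01 with normexp background correction. Integrin and adhesion genes had a median of -0.46 (percentile 0.11), although 7 of 32 were higher and 5 lower past 2-fold. Itga9 read -5.65 under the label against -2.45, and Itgb2 -1.26 against 1.04, while Itgae and Itgb7, also in this list, were higher.

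Growth genes were lower as groups under the Pla2g3-/- label in coculture. Cell cycle genes were lower in 40 and higher in 0 of 44 (median -2.11), with Top2a 6.79-fold and the nucleotide reductase Rrm2 6.33-fold lower. Cholesterol synthesis genes were lower in 22 and higher in 0 of 24 (median -1.58), with Cyp51 6.67-fold and Idi1 6.23-fold lower. Immediate early genes were lower in 25 and higher in 1 of 32 (median -3.03), the higher one being Btg2 (4.28-fold), an antiproliferative gene. Cytokine genes were lower in 15 and higher in 4 of 27 (median -1.23), the higher ones including Il1b (15.5-fold) and Il4 (2.98-fold). Unfolded protein and amino acid response genes were lower in 14 and higher in 1 of 29 (median -0.94), and hypoxia and glycolysis genes lower in 8 and higher in 3 of 27 (median -0.44). Interferon response genes were higher in 10 and lower in 6 of 33 (median 0.27, percentile 98.88), a call lost with the other wild-type array (median 0.08). Among the highest genes besides Pla2g3 were Trim12a (353-fold; chromosome 7, 111448499 to 111448558), Tescl (78.7-fold), Ahrr (71.5-fold), a repressor of the aryl hydrocarbon receptor, Tbx6 (36.3-fold) and Ctse (34.5-fold), and Lpar6 was 17.1-fold higher.

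Fibroblast and matrix genes were lower in 19 and higher in 1 of 47 (median -0.70) on the array labelled Pla2g3-/- in coculture, with Dcn 5.45-fold and Vcam1 4.31-fold lower. Macrophage and dendritic genes were lower in 10 and higher in 2 of 24 (median -0.68), with Trem2 27.3-fold and Mrc1 at least 52.5-fold lower. Neutrophil and eosinophil genes went both ways, 4 higher and 4 lower of 21 (median -0.50, a call lost with normexp), with Ccr3 3.02-fold and Siglecf 2.76-fold higher and S100a8 4.15-fold and S100a9 3.89-fold lower. Of 22505 genes, 2049 were higher and 2345 lower. With the other wild-type coculture array, 2251 were higher and 2859 lower, of which 1868 and 2109 were shared.

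In coculture with Lpar1-/- fibroblasts, the wild-type mast cell fraction had lower signal of stimulation, growth and connective tissue mast cell genes. These fibroblasts were a single-cell clone on 1 array, so clone and deletion cannot be told apart for any of these genes. Fibroblast transcripts were abundant in this RNA (Col1a2 at 2.84 and Sparc at 3.31), so the cell of origin is not settled for genes that both cells express. Tnf was 958-fold, Mrgprb1 268-fold, Egr2 135-fold, Fosb 90.7-fold, Ccl7 46.6-fold and Nr4a1 38.6-fold lower. Tpsab1 was 23.7-fold, Hdc 9.74-fold, Mcpt4 4.64-fold and Tpsb2 2.33-fold lower. Of 12 connective tissue genes, 6 were lower and 0 higher (median -0.88, percentile 0.02). Cma1 (-0.53), Hpgds (-0.38), Ms4a2 (-0.34), Cpa3 (-0.07), Fcer1a (-0.08), Ptgds (-0.07), Enpp2 (0.29), Kit (0.36) and Ndst2 (0.89) stayed within 2-fold on the log2 scale, and Pla2g3 was 3.34-fold higher by its brightest probe alone. Its probe at 3393127 to 3393186 read -7.11 with wild-type and -7.35 with Lpar1-/- fibroblasts, and the other probe was not well above background on either array.

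With Lpar1-/- fibroblasts, cell cycle genes were lower in 39 and higher in 0 of 44 (median -2.17), with Mki67 10.1-fold and Nusap1 10.7-fold lower. Cholesterol synthesis genes were lower in 23 and higher in 0 of 24 (median -1.95), with Hsd17b7 10.5-fold and Cyp51 9.48-fold lower. Immediate early genes were lower in 26 and higher in 1 of 32 (median -2.40), cytokine genes lower in 15 and higher in 6 of 30 (median -1.03), and unfolded protein and amino acid response genes lower in 16 and higher in 1 of 29 (median -1.17). Hypoxia and glycolysis genes were lower in 8 and higher in 2 of 27 (median -0.58). The mucosal list was higher in 5 and lower in 3 of 9 (median 1.17), with Mcpt1 27.1-fold, Itgae 19.1-fold, Mcpt2 4.15-fold and Itgb7 3.64-fold higher, whereas Mcpt8 was 3.55-fold lower. Il1b (12.7-fold) and Lpar6 (18.4-fold) were higher, as on the array labelled Pla2g3-/- in coculture.

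Fibroblast and matrix genes went both ways in the Lpar1 comparison, with 14 higher and 7 lower of 48 (median 0.20). Thy1, a surface marker of fibroblasts that other cells also express, was 196-fold higher, the stromal genes Dlk1 and Grem1 80.8-fold and 66.1-fold, the smooth muscle actin gene Actg2 76.7-fold and Ccn2 11.5-fold higher, whereas Vcam1 was 3.79-fold lower. Neutrophil and eosinophil genes were higher in 12 and lower in 0 of 23 (median 1.14), with Prg2 7.99-fold and Ltf 5.54-fold higher, and Cd24a was 41.8-fold higher. Macrophage and dendritic genes were lower in 6 and higher in 2 of 26 (median -0.21, not apart, and -0.50 and apart with the other wild-type array), with Mrc1 37.7-fold and Clec7a 8.86-fold lower and Cx3cr1 7.24-fold and Itgax 6.32-fold higher. Housekeeping genes had a median of -0.39 (percentile 1.89), with 2 of 26 lower and the call lost with the other wild-type array, and that of ribosomal protein genes was -0.14. Lce1g (109-fold higher) belongs to a family of similar genes and is uncertain. Pcdh10, at least 937-fold lower here, differed by 8.16 on the log2 scale between the wild-type cocultures, so that value rests on 1 wild-type array. Of 24545 genes, 2770 were higher and 2170 lower. With the other wild-type array, 2665 were higher and 2078 lower, of which 2345 and 1844 were shared.

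**Figure D3:**
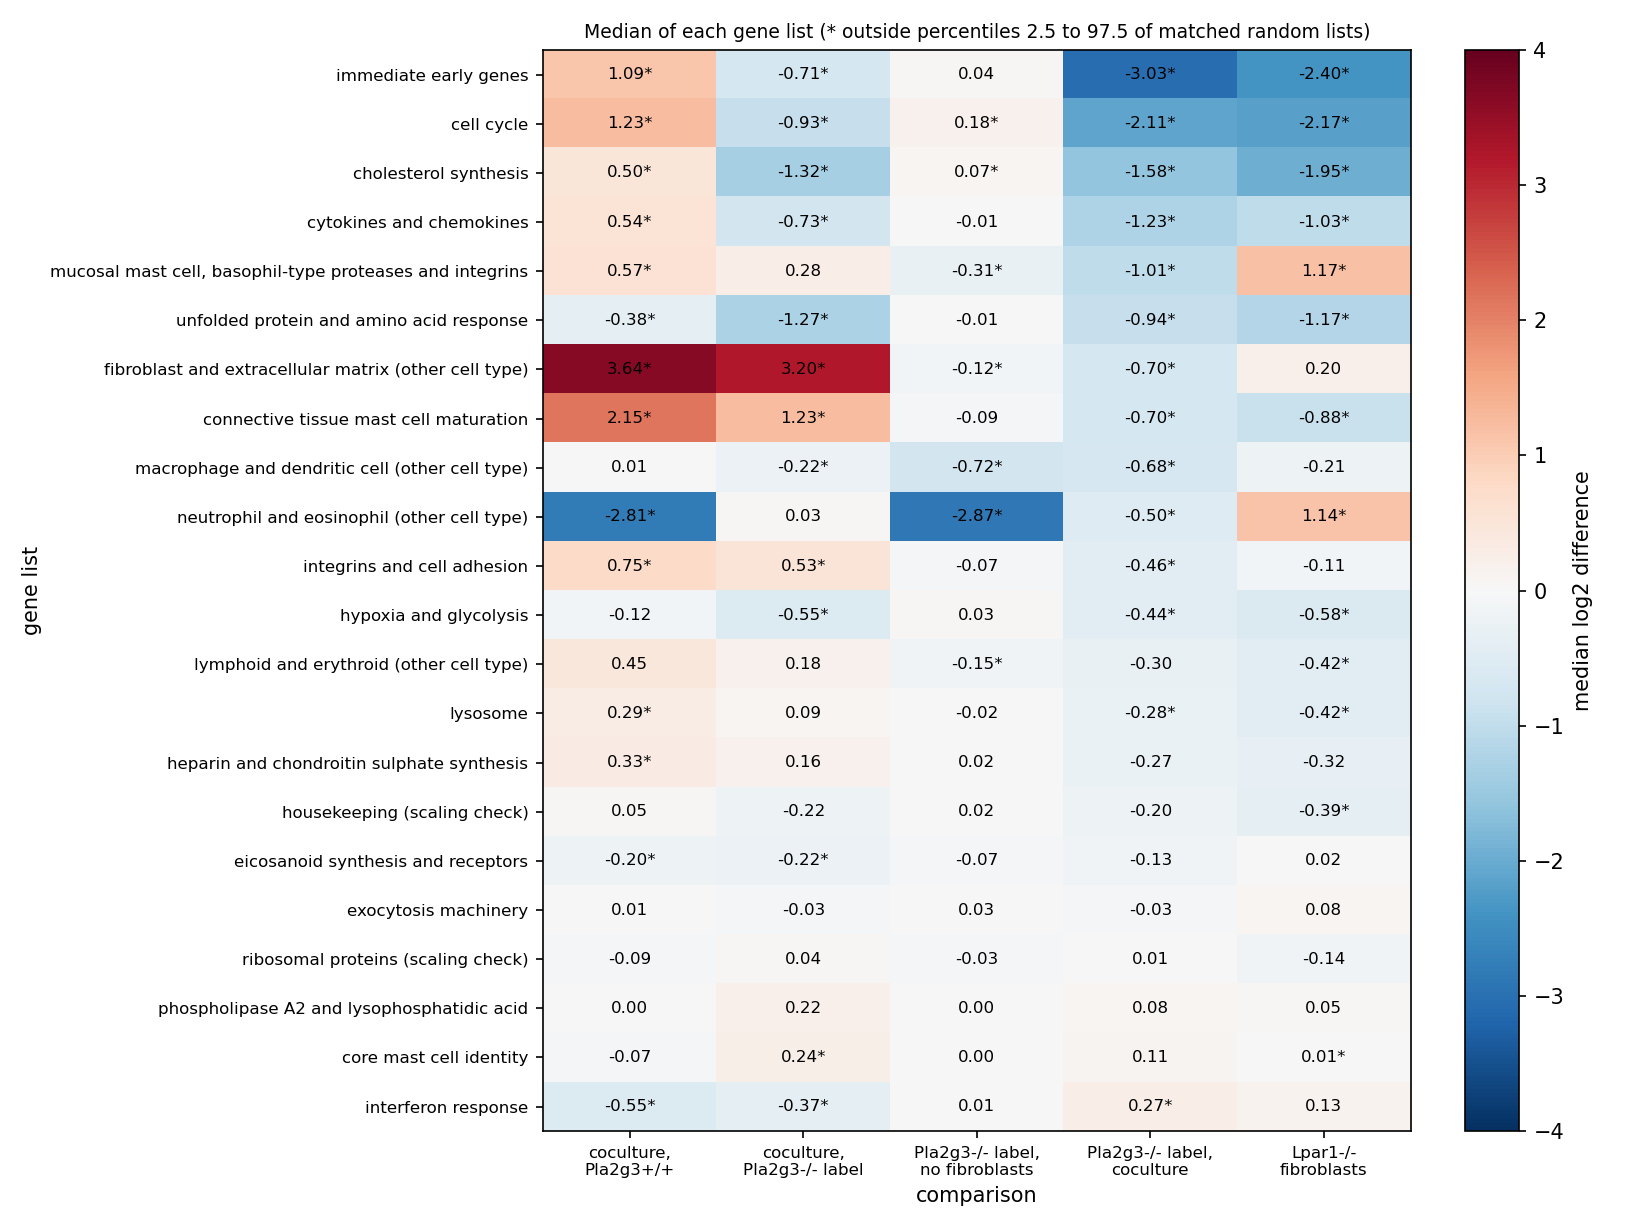
Median log2 difference (colour and printed value) of each of 22 gene lists (vertical axis) in the 5 comparisons (horizontal axis), with an asterisk where the median lies outside the range that called a list apart from matched random lists. Cell cycle, cholesterol and immediate early genes are higher in coculture of Pla2g3+/+ cells (1.23, 0.50 and 1.09) and lower in the last columns, with -2.11, -1.58 and -3.03 under the Pla2g3-/- label and -2.17, -1.95 and -2.40 with Lpar1-/- fibroblasts.

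The coculture differences under the Pla2g3-/- label and with Lpar1-/- fibroblasts, which shared no array, correlated across 20754 genes with r = 0.86 and rho = 0.83. Higher in both were 1625 genes, where independent lists would share 224, lower in both were 1384, against 180, and 30 went in opposite directions. Across 12452 genes expressed in the cells without fibroblasts, r was 0.93 and rho 0.91. Without and with fibroblasts, the differences under the Pla2g3-/- label, which also shared no array, correlated with r = 0.17 and rho = 0.07 across 19768 genes. Of the 2-fold genes, 24 were higher in both, where independent lists would share 4.53, 106 were lower in both, against 20.3, and 17 went in opposite directions.

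**Figure D4:**
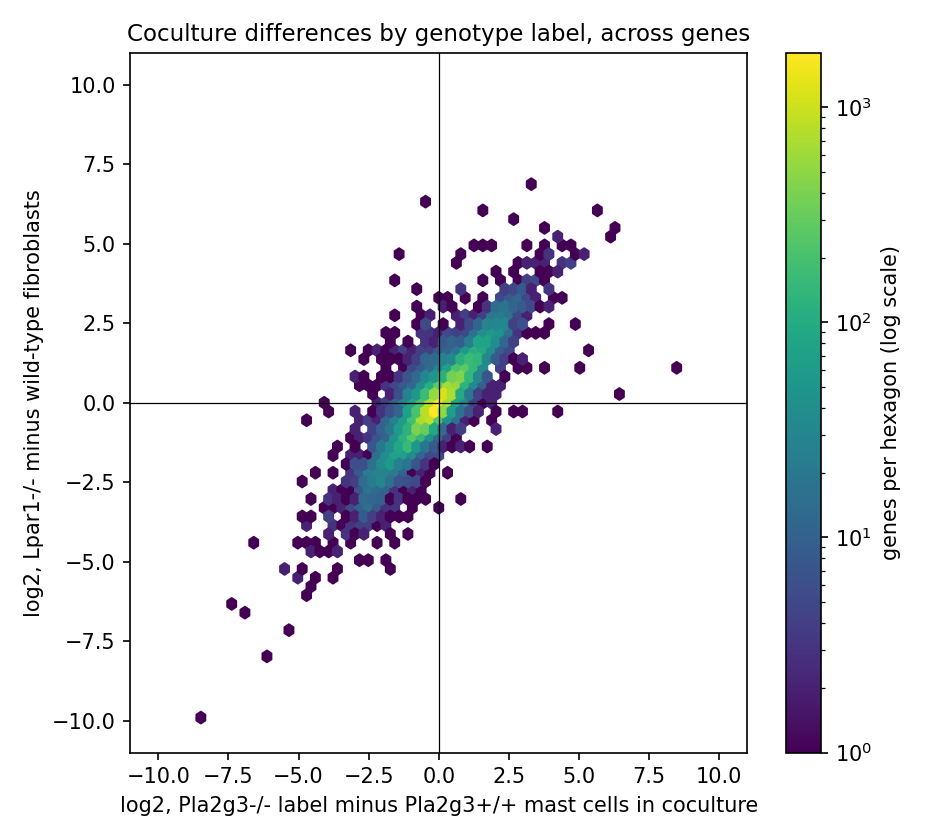
Log2 difference under the Pla2g3-/- label in coculture (horizontal axis) against that with Lpar1-/- fibroblasts (vertical axis) for 20754 genes, with colour giving the number of genes per hexagon on a log scale. Genes spread along the rising diagonal (r = 0.86 across genes), from Tnf at -8.52 and -9.90 at the lower left, while Trim12a at 8.46 lies far to the right.

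Genes that coculture raised or lowered were then followed under the Pla2g3-/- label and with Lpar1-/- fibroblasts, on arrays not used to choose them. The wild-type coculture used for choosing and the one used for scoring were the same condition, with a correlation of 0.998 across genes. A coculture that departed from that state in any way would tend to show raised genes lower and lowered genes higher. The matched random lists do not correct for this, so the percentiles are no independent test. Of 2949 genes higher in the second wild-type coculture, 2870 were measured under the Pla2g3-/- label, where 1196 were lower and 65 higher (median -0.83, percentile 0). Of 1739 coculture-lowered genes, 1629 were measured, with 828 higher and 87 lower (median 1.03, percentile 100). With Lpar1-/- fibroblasts, 2946 of 2948 coculture-raised genes were measured, 1036 lower and 181 higher (median -0.57, percentile 0), and of 1669 coculture-lowered genes 931 were higher and 53 lower (median 1.17, percentile 100). The raised genes also hold fibroblast transcripts, and 845 of the 2948 were among genes expressed without fibroblasts. The fibroblast list had medians of 3.64 in coculture of Pla2g3+/+ cells, -0.70 under the label and 0.20 with Lpar1-/- fibroblasts. A change in fibroblast RNA is therefore mixed into the raised sets, and their medians do not describe mast cells alone.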

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

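Of the tests in this part, those on linked DNA and on the fibroblast clone were chosen beforehand, and the other 8 were chosen only after the result was seen, as was the counting-spread limit used for the clone.

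Coculture effects on 4 gene lists had opposite signs in the mast cell genotypes, each apart from matched random lists on both sides in the main setting, and the difference itself was not tested because each group had 1 array. From Pla2g3+/+ cells to cells labelled Pla2g3-/-, the cell cycle median went from 1.23 to -0.93 (difference -2.16), cholesterol synthesis from 0.50 to -1.32 (-1.82), immediate early genes from 1.09 to -0.71 (-1.81) and cytokines from 0.54 to -0.73 (-1.27). The cytokine list of the Pla2g3+/+ cells, with 11 higher and 11 lower, was no longer apart with normexp, quantile normalization, the mean of probes or the other filters on dim probes.

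The coculture labelled Pla2g3-/- and that with Lpar1-/- fibroblasts moved together relative to their wild-type arrays, which might reflect a shared biological response or a shared handling of the cultures. RNA of fibroblasts as the whole cause is argued against by the correlation of 0.929 over genes expressed without fibroblasts, and 1 pool hybridised as both by the 1475 genes that differed between these cocultures, against 233 between the wild-type ones. A weaker coculture response could account for part of the connective tissue list. Its median against no fibroblasts was 1.00 with Lpar1-/- fibroblasts, between 0 and the wild-type 2.15. For Hdc with Lpar1-/- fibroblasts a weaker response falls short, at -0.97 there and 0.83 in Pla2g3+/+ cells without fibroblasts. Under the Pla2g3-/- label it could account for Hdc, at 0.46 in coculture and 0.26 without fibroblasts. A weaker response also falls short for cell cycle genes, whose medians of -0.93 and -0.96 lay below the cells without fibroblasts. Those cells lay on another slide, as for the wild-type 1.23. Less growth factor signal at harvest would also lower immediate early genes (medians -3.03 and -2.40) and cannot be told apart from genotype, since the design gives no array that separates them. The biological explanation, loss of a signal that both genes serve, stays open and untested.

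Pla2g3 probes were brighter under the Pla2g3-/- label. A swap of the Pla2g3 labels is argued against by the second wild-type coculture, which was dim, 4.75 below the array labelled Pla2g3-/- on the log2 scale, and 1 cross-hybridising probe by the fact that 3 of 3 probes were brighter. Linked DNA carried with the allele is argued against as the source of the other label-dependent genes, since 0.599% of 167 such genes lay within 10 Mb of Pla2g3, against 0.526% of all tested genes. A transcript that the modified allele still makes, and a strain difference elsewhere in the genome, may remain as explanations and were not tested.

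Fibroblast transcripts differed with fibroblast Lpar1. A different amount of fibroblast RNA as the whole cause is argued against by members on both sides, 29.2% of the measured list higher and 14.6% lower, although selection of Kit-positive cells, if used, would remove most fibroblasts. Of the 49 genes of this list 26 were well above background without fibroblasts too. Several of its abundant genes in coculture that lay below -3 on both arrays without fibroblasts stayed within 2-fold, with Sparc at -0.47, Col1a2 at -0.08 and Fn1 at -0.25. Others of that kind moved past 2-fold, with Vcam1 at -1.92 and Ddr2 at -1.56 lower and Nid1 at 1.41 higher. The Lpar1-/- fibroblasts were a single-cell clone, and clone properties could add to this: of 401 differences past 8-fold, 56.6% were in genes below -3 on both arrays without fibroblasts, against 51.6% of 225 in the Pla2g3 comparison. That share was larger as foreseen, but the gap of 5.05 points was under 2 standard errors (4.15 each), which treat genes as independent. Clone properties and Lpar1 deletion lay in the same fibroblasts and could both raise this share. A gap of any size would therefore leave clone and Lpar1 deletion impossible to tell apart.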

How the results depend on the processing

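The settings restricted to genes expressed without fibroblasts, to a brighter array above -5, and to another baseline were chosen after the data were seen, and the rest were planned. Counting each value once per setting, 4390 named-gene values, 914 list medians and 32 medians of coculture sets kept their direction and side of the threshold, 142 counts stayed within 1.5 times the main count, and 24 correlations stayed within 0.1. Of the named genes 125 lost and 4 gained the 2-fold call, and of the lists 30 lost and 21 gained the percentile call. These totals overstate how far named genes were tried. The deposited value table is the same signal divided by a constant, and the settings for dim probes leave genes well above background on both arrays unchanged. With normexp, which could move them, 440 named-gene values stayed the same, 87 lost the 2-fold call and 1 reversed. The cause was not tested unless stated. Signal over background limits the counts, with 70.7% to 80.4% of spots well above it. With normexp 17 counts moved and with no filter on dim probes 11, while the restriction to genes expressed without fibroblasts moved 12. The other settings for dim genes moved fewer: 4 with the brighter array above -5, 3 with signal required on the compared arrays and 2 with measured differences. No paired analysis was possible because the labels give no replicate numbers and each group has 1 array.

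Normexp with its offset pulls dim signals together, so fewer genes passed 2-fold: 1396 higher and 1035 lower in coculture of Pla2g3+/+ cells, 1108 and 912 under the Pla2g3-/- label, 23 and 93 for the label without fibroblasts, 1339 and 1209 for it in coculture, 1591 higher with Lpar1-/- fibroblasts, 4 and 0 between the wild-type cocultures, and 1380 and 1156 for the difference of coculture effects. Shared genes fell to 1065 higher both under the label and with Lpar1-/- fibroblasts, 429 higher and 329 lower in both coculture comparisons, and 36 lower under the label with and without fibroblasts. Under the label in coculture, the mucosal median reversed to 0.0112 and Mcpt9, then its middle member, to the same 0.0112. Quantile normalization gave 171 lower genes between the wild-type cocultures. The near-zero core mast cell median with Lpar1-/- fibroblasts reversed to -0.0429 with median centring and to -0.10 with the other wild-type array. With the mean of probes, Cplx2 in coculture under the label reversed to -0.55, and the connective tissue median without fibroblasts, -0.0883, passed the percentile.

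Requiring signal on both compared arrays, which leaves out the bounds, left 53 higher genes for the label without fibroblasts. Between the wild-type cocultures it left 83 higher and 23 lower, since fewer genes were tested. With no filter on dim probes, counts grew to 3205 lower in coculture under the label, 722 higher and 994 lower for the label without fibroblasts (42.1% higher), 4007 lower for it in coculture, 1438 and 370 between the wild-type cocultures, and 4361 lower for the difference of coculture effects. The connective tissue median under the label in coculture became -0.26 and lost the call, the correlation of the label with the Lpar1 comparison became 0.72, and shared genes became 1724 higher and 843 lower in both coculture comparisons, and 71 higher and 338 lower under the label with and without fibroblasts. Measured differences in place of bounds gave 192 higher genes for the label without fibroblasts and 782 between the wild-type cocultures.

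Among genes expressed without fibroblasts, which are fewer by construction, 845 were higher and 982 lower in coculture of Pla2g3+/+ cells (46.3% higher), 684 and 1026 under the label (40.0% higher), 16 and 39 for the label without fibroblasts, 1101 and 1025 for it in coculture, 1270 and 1222 with Lpar1-/- fibroblasts, and 3 and 0 between the wild-type cocultures. With the brighter array above -5, 37 and 183 genes differed for the label without fibroblasts and 10 and 4 between the wild-type cocultures.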

Other observations

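The observations in this part were chosen only after the values were seen, and no explanation was tested for them.

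A set of 170 genes other than Pla2g3 differed at least 2-fold the same way under the Pla2g3-/- label in all 3 comparisons, without fibroblasts and in coculture against each wild-type array, 35 higher and 135 lower. Both coculture comparisons use the same array labelled Pla2g3-/-, and the wild-type arrays correlated at 0.998, so the second adds little to the first. Sharing was counted for the comparison without fibroblasts and the first in coculture, over a narrower set of 19768 genes. Without fibroblasts, 48 of these were higher and 224 lower, against 92 and 344 of all 21752 genes compared. Of the 19768 genes, 24 were higher in both and 106 lower in both, where independent lists would share 4.53 and 20.3. Those counts leave out part of the 170 genes, so the values for independent lists do not apply to the 170. The highest of the 170 was Trim12a, at 7.40 without fibroblasts and 8.46 in coculture on the log2 scale. Other high ones were Tescl at 5.82 and 6.30 and Ctse at 4.66 and 5.11. The lower ones included Stfa1 (-4.84 without fibroblasts and -3.09 in coculture) and Pf4 (-4.79 and -2.89). In the granulocyte or macrophage lists were 12 of the 170. These directions rest on the label, which Pla2g3 itself went against.

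Heparin and chondroitin sulphate synthesis genes were higher as a list in coculture of Pla2g3+/+ cells (median 0.33, percentile 99.38), with 6 of 32 higher, among them Xylt1 (6.62-fold) and Ext1 (2.91-fold), and Chsy1 4.90-fold lower. Lysosomal genes had a median of 0.29 there, with Ctsl 7.92-fold and Lgmn 4.58-fold higher, and medians of -0.28 under the Pla2g3-/- label and -0.42 with Lpar1-/- fibroblasts, calls lost with normexp and with the other wild-type array respectively. Exocytosis genes had medians between -0.03 and 0.08 in the 5 comparisons. Lymphoid and erythroid genes had a median of -0.42 with Lpar1-/- fibroblasts, with 3 of 17 lower, a call lost with normexp, quantile normalization, no filter and the other wild-type array.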
